A study of Homo sapiens with 4 samples.

How the data were processed

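RNA sequencing libraries were made from HCT116 cells, a human colon cancer line with high microsatellite instability and deficient mismatch repair, and from HCT116 CH3+5, a derivative that is microsatellite stable after transfer of chromosomes 3 and 5. Each line was transfected with a scrambled control siRNA or with an siRNA against WRN at 0.2 µM, and RNA was taken after 36 h by the Trizol method. The 4 libraries form 4 groups of 1 library each. Nothing in the labels describes separate cultures, so there was no replicate with which to measure variation between cultures.

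Per the submitters' processing notes, reads from an Illumina HiSeq instrument were handled with HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.20.0 and edgeR 3.22.5 on genome build hg38. The strand setting, the handling of reads that map to several places and any filter on reads are not given in the sources used here. The authors deposited 1 table of integer read counts for 58735 genes. A second deposited table gives FPKM (fragments per kilobase of gene, scaled to the library total) for the same 4 libraries. The deposited FPKM equalled FPKM recomputed from the counts, gene lengths and total counts, times 1 constant per library, which lay between 0.951 and 1.02 and whose source is not stated. The deposited FPKM table was joined to the counts by gene name, and 1745 genes with repeated names were left out of that join.

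The libraries held 20689896 counts (parental, control siRNA), 18664677 (parental, siWRN), 20005679 (CH3+5, control siRNA) and 21526562 (CH3+5, siWRN). A count of 0 allows up to 3 counts, which is 0.141, 0.161, 0.152 and 0.142 CPM (counts scaled to library size) in that order. Intervals and this floor cover counting error only, because reads without molecular identifiers are not independent molecules and because variation between cultures was not measured.

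Genes with at least 1 CPM in at least 1 of the 4 libraries were kept (15917 genes). Counts were scaled with TMM factors in edgeR 4.0.16 (R 4.3.3), and log2 fold changes were taken from log2 CPM with a prior count of 2. A gene passed the size rule when the fold change reached 1.5 in either direction and the exact 95% Clopper-Pearson interval of its count ratio excluded 1. The words rose, fell, higher and lower are used for genes that passed this rule, and no p-value is given for a comparison of 1 library with 1 library. The comparisons were siWRN against control siRNA in the parental line, the same in CH3+5, CH3+5 against the parental line under control siRNA, and the difference of the 2 siWRN changes (parental minus CH3+5). For that difference the interval was a 95% normal interval on the log of counts plus 0.5. CH3+5 was also compared with the parental line in the siWRN libraries.

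An additive model (line plus siRNA) was fitted to the 4 libraries with the edgeR quasi-likelihood F test, with Benjamini-Hochberg adjustment over all 15917 genes at 0.05. It has 1 residual degree of freedom, and its error term contains the line-by-siRNA difference as well as noise. It therefore asks for changes of like size in both lines. DESeq2 1.42.0 and limma 3.58.1 (limma-voom) served as other tools.

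The 25 gene lists were written from general knowledge and hold 545 distinct genes, 451 of their 556 entries being measured. They cover p53 targets, pro-apoptotic and anti-apoptotic BCL2 relatives, G1/S and replication, G2/M and mitosis, replication-dependent histones, mismatch repair, RecQ helicases, homologous recombination and Fanconi anaemia, interferon-stimulated genes, antigen presentation, NF-kB and cytokines, ATF4 and the unfolded protein response, cholesterol synthesis, immediate early genes, hypoxia and glycolysis, TGF-beta targets, Wnt targets, epithelial and colon genes, mesenchymal genes, leukocyte genes, endothelial genes, mitochondrially encoded mRNAs, ribosomal proteins and common reference genes. The median log2 fold change of a list was placed as a percentile among 10000 random lists of equal size matched on mean expression in 20 bins. Percentiles of 0 and 100 mean that no random list lay beyond the median. Genes within a list are not independent, so the percentile is a rank and not a test of replication. Chromosomes were treated in the same way, and medians were also taken in windows of 10 Mb with at least 10 measured genes.

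The comparisons, the lists, the filters and the rule for naming genes were fixed before the data were examined. The rule named a fixed set of genes always (WRN, BBC3, CDKN1A and MSH3 among them), the 8 largest changes in each direction among protein-coding genes that passed the size rule with at least 100 counts in the higher library, the 5 smallest p-values in each direction among genes with an adjusted p under 0.05 in the additive model, and up to 4 members per list with the largest changes past the size rule (up to 2 where none passed). Genes named outside the rule are marked as chosen after their values were seen. Some genes that the rule names, 1 Y-linked gene among them, are not reported here. Gene positions are those of the deposited count table on hg38.

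Most alternatives changed 1 choice at a time: DESeq2 size factors, total counts only, no filter on low counts, a filter at 5 CPM, a 2-fold rule, a prior count of 5, counts thinned to the smallest library, protein-coding genes only, and the other tools for the additive model. The deposited FPKM, as log2 of FPKM plus 1, changed several choices together. Genes with repeated names were left out, and the 1.5-fold limit was applied without a counting interval. Random lists numbered 2000 for the alternatives of gene lists and 1000 for those of chromosomes. After the data were seen, 2 alternatives were added: removal of trends with GC content and gene length (medians of 20 bins each, over the 15909 tested genes with a sequence in the reference transcript set), and omission of genes on chromosomes 3 and 5.

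The pipeline was tested on simulated data with 200 changed genes and an assumed biological coefficient of variation of 0.1. In the parental comparison 38 of 67 genes changed 1.5-fold, 64 of 67 changed 2-fold and 66 of 66 changed 4-fold passed the size rule, as did 431 of 15717 unchanged genes (2.74%). In a simulated CH3+5 comparison without any change, 389 of 15717 genes passed. The additive test recovered 41 of 67, 67 of 67 and 66 of 66 genes at those folds, with 11 of 14907 unchanged genes called. Changed genes were drawn from those above 5 CPM on average, and in the additive simulation they changed equally in both lines. The fit to the real libraries had a larger common coefficient of variation, 0.199, so these recoveries do not measure the power of the real test. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.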

Results

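The study asked why colon cancer cells that lack mismatch repair depend on WRN, a RecQ helicase that unwinds DNA at stalled replication forks, and what part p53 and its target PUMA (gene BBC3) have in it. In the parental HCT116 line, siRNA against WRN lowered WRN mRNA, and most p53 target, immediate early, and NF-kB and cytokine genes were higher and most DNA replication and mitosis genes lower. In HCT116 CH3+5, the derivative with transferred chromosomes 3 and 5, the library labelled siWRN held 0.829 of the control level of WRN, so WRN was not depleted there, and few genes of those groups differed. The contrast between the lines can therefore not separate mismatch repair status from the absence of a knockdown. Nor can it separate that status from the other differences between the lines, since under control siRNA 2687 genes were higher and 2748 lower in CH3+5. Each group was 1 library of 18664677 to 21526562 counts, and no difference has a replicate check.

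The genes the study is about set the frame for the other comparisons. WRN (ENSG00000165392, chromosome 8, 31033801 to 31173769, hg38) went from 732 counts to 109 in the parental line, from 34.4 to 5.87 CPM, a level 5.86 times lower (95% counting interval 4.79 to 7.24). In CH3+5 it went from 901 counts to 801, from 45.7 to 37.9 CPM, with a ratio of 0.829 (0.753 to 0.913). BBC3 (ENSG00000105327, chromosome 19, 47220822 to 47232766), which encodes the pro-apoptotic protein PUMA, rose 2.74-fold in the parental line (2.47 to 3.04), from 24.2 to 66.3 CPM. In the CH3+5 libraries BBC3 stood at 13.0 CPM with control siRNA and at 10.9 CPM in the library labelled siWRN, a log2 change of -0.25 (-0.52 to 0.01). CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339), which encodes the cell cycle inhibitor p21, rose 6.52-fold in the parental line (6.33 to 6.72), from 245 to 1598 CPM, against 209.6 and 208 CPM in CH3+5. MSH3 (ENSG00000113318, chromosome 5, 80654648 to 80876460) encodes a mismatch repair protein on a transferred chromosome. Under control siRNA, MSH3 was 4.37-fold higher in CH3+5 than in the parental line (3.50 to 5.50), at 20.3 CPM against 4.65. It did not pass the size rule between siRNAs in either line.

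**Figure D1:**
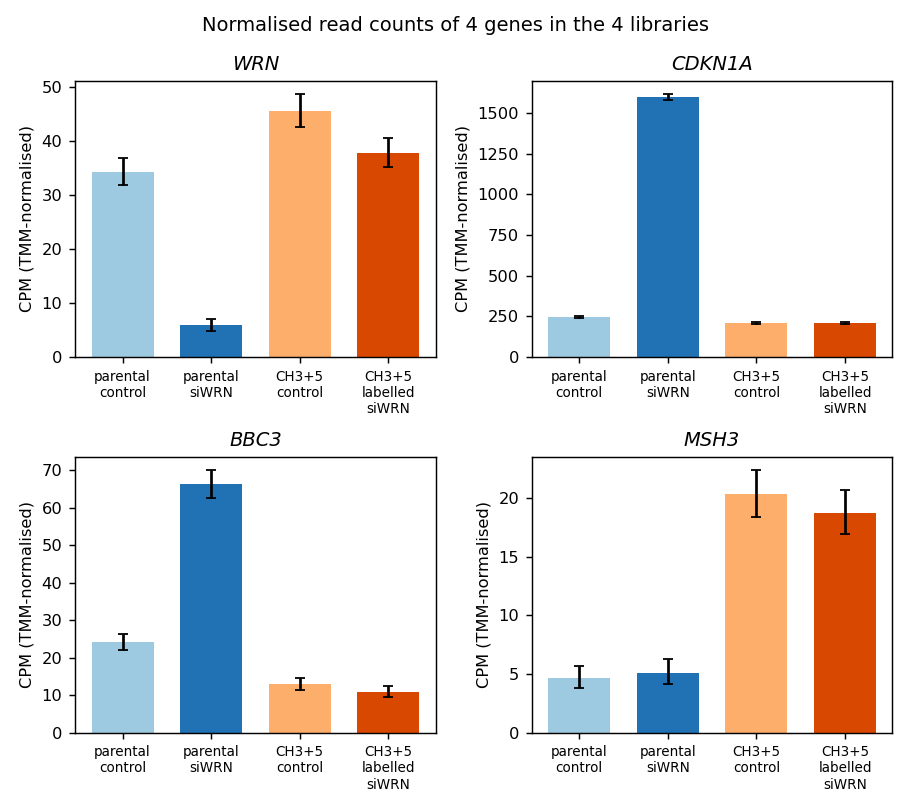
Normalised read counts (CPM, vertical axes from 0) of WRN, CDKN1A, BBC3 and MSH3 as columns for the 4 libraries, with error bars for the 95% counting interval. WRN lay at 34.4 and 5.87 CPM in the parental libraries and at 45.7 and 37.9 CPM in the CH3+5 libraries.

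In the parental line, where WRN was lowered, many p53 target and cell cycle genes differed between the siWRN library and its control. Most genes that p53 switches on rose, and most genes of S phase, mitosis and homologous recombination fell. Most immediate early and NF-kB and cytokine genes rose with them, while most cholesterol synthesis genes fell. Of 15917 genes, 1516 were higher and 2470 lower, and at 2-fold 663 and 1332, at 5 CPM 953 and 1547, and with the deposited FPKM 889 and 1201.

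Of 50 measured p53 targets, 35 were higher and 1 lower in the parental siWRN library, with a median log2 change of 0.91 (percentile 100 of matched random lists). The largest changes among them were CDKN1A, the antiproliferative gene BTG2 at 2.53, the stress sensor SESN2 at 2.50 and the kinase gene PLK2 at 1.93, and the lower gene was KITLG, the ligand of KIT, at -0.69. Further targets, chosen after their values were seen, were MDM2, the ubiquitin ligase that restrains p53, at 1.11, the death receptor FAS at 1.71 and GADD45A, a gene of the DNA damage response, at 1.79. Of 11 pro-apoptotic BCL2 relatives, 3 were higher and 1 lower (median 0.40, percentile 99.4): BBC3, BAK1 at 1.15 and PMAIP1, which encodes NOXA, at 1.12 rose, and BMF fell at -0.88. Of the 4 anti-apoptotic relatives, MCL1 was higher at 0.82 and BCL2 lower at -1.29 (median 0.16, percentile 75.4).

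Of 34 genes of G1/S and replication, 29 were lower and 0 higher in that library (median -1.07, percentile 0). They included the thymidine kinase TK1 at -1.84, the replication fork gene GINS1 at -1.63, the transcription factor E2F1 at -1.60 and the checkpoint mediator CLSPN at -1.48. All 34 measured genes of G2/M and mitosis were lower (median -1.18, percentile 0), among them CENPF at -1.86 and CENPA at -1.61 of the centromere, the spindle protein PRC1 at -1.78 and the kinase NEK2 at -1.65. Homologous recombination and Fanconi anaemia genes were lower in 17 of 28 cases and higher in 0 (median -0.70, percentile 0), with BRCA2 at -1.84, RAD54B at -1.64, RAD54L at -1.52 and BRCA1 at -1.34. Besides WRN, the RecQ helicases BLM at -1.28 and RECQL4 at -0.91 were lower (3 of 5 genes, median -0.91, percentile 0.05). That median and percentile include WRN, the target of the siRNA, so they are in part set by the knockdown. In mismatch repair, 3 of 8 genes were lower, EXO1 at -0.96 and MSH6 at -0.91 among them (median -0.25, percentile 6.41, or -0.33 at percentile 1.70 after removal of GC and length trends). Histone genes went the other way, with 7 of 8 higher (median 0.99, percentile 100), led by HIST1H2BC at 2.0 and HIST2H2BE at 1.54. Of the 20 listed histone genes in the deposited counts, only these 8 passed the filter, so the others are not covered.

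Several signalling and stress lists had medians above 0 in the same library. Immediate early genes, which respond within minutes to growth factors and stress, were higher in 15 of 19 cases (median 1.55, percentile 100), with JUN at 2.65, EGR1 at 2.33 and FOS at 2.11. NF-kB and cytokine genes were higher in 9 of 14 cases (median 1.23, percentile 100). The neutrophil chemokine CXCL8 went from 5 to 253 counts, 58.0-fold (24.5 to 180), BIRC3, an inhibitor of apoptosis, was at 2.75, and CXCL2 and CXCL1 were higher from 3 counts each to 31 and 24. TGF-beta targets were higher in 11 of 22 cases and lower in 2 (median 0.80, percentile 100), with CTGF at 2.31 and THBS1 at 1.81 higher and the inhibitory SMAD6 at -1.81. ATF4 and unfolded protein response genes were higher in 8 of 19 cases and lower in 1 (median 0.50, percentile 100), with PPP1R15A, which restarts translation, at 2.13, the chaperone gene DNAJB9 at 2.02 and DDIT3 at 1.79. Hypoxia and glycolysis genes were mixed, 5 higher and 2 lower of 23 (median 0.19, percentile 96.6), with the glucose transporter SLC2A3 at 1.26 and ALDOC at -1.43. Among the largest rises were also the keratin-associated gene KRTAP2-3 at 4.10, the stress transcription factor ATF3 at 3.03, the hexokinase-related HKDC1 at 2.97, the uridine phosphorylase UPP1 at 2.80 and the haem oxygenase HMOX1 at 2.77.

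Most genes of cholesterol synthesis fell. They were lower in 12 of 20 cases and higher in 1 (median -0.66, percentile 0), with INSIG1 at -1.08, LSS at -1.03 and the transcription factor SREBF2 at -0.99. Wnt targets were lower in 5 of 15 cases and higher in 2 (median -0.32, percentile 0.78), with the Wnt inhibitors NOTUM at -1.82 and NKD1 at -1.25. Among protein-coding genes with at least 100 counts in the higher library, the 8 largest falls were ANK1, a membrane skeleton gene, at -3.94, PRIMA1 at -3.70, the methyltransferase-like METTL7A at -3.47, the water channel AQP3 at -3.40, the calcium-binding CALB1 at -3.27, the inositol transporter SLC5A3 at -2.94 (4398 to 497 counts), the cytochrome CYP1A1 at -2.89 and AGFG2 at -2.85. Interferon-stimulated genes were lower in 7 of 22 cases and higher in 1 (median -0.34, percentile 2.95, or -0.39 at percentile 0.90 after removal of GC and length trends), with IFIT1 at -2.63, IFIT3 from 37 to 9 counts, and IFI44 from 1 to 7 counts as the higher gene. In antigen presentation 2 of 16 genes were higher, TAP1 at 0.90 and HLA-B at 0.62, and NLRC5 was lower at -0.78 (median 0.08, percentile 71.3).

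Lists of cell identity were also counted in the parental siWRN library. Of 14 epithelial and colon genes, KRT19 was higher at 1.01 and 3 were lower, CLDN3 at -1.46, KRT20 at -1.19 and ELF3 at -1.02 (median -0.10, percentile 20.3). Of 10 mesenchymal genes 4 were higher and 3 lower (median 0.28, percentile 95.4), S100A4 among the latter at -2.65. Among 3 leukocyte genes CORO1A was lower at -0.97, and of 4 endothelial genes 2 were lower, PECAM1 from 66 to 0 counts and VWF from 21 to 6. No mitochondrially encoded mRNA of 13 and no ribosomal protein gene of 40 passed the size rule, but their medians of 0.27 and 0.19 lay high among random lists, at percentiles 99.3 and 99.9. After removal of GC and length trends the mitochondrial median was 0.21, inside the central 95% of random lists. Of 15 common reference genes 1 was higher and 0 lower (median 0.05).

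In CH3+5, the library labelled siWRN was close to its control for cell cycle, p53 and stress genes. WRN was at 0.829 of control there, so this pair of libraries does not show what loss of WRN does in CH3+5. Of the 15917 genes, 373 were higher and 560 lower, and the log2 changes had an SD of 0.40 against 0.71 in the parental line. Many of these were genes with low counts, since 96 were higher and 118 lower with a filter at 5 CPM, against 767 and 979 without a filter, and with the deposited FPKM 110 and 155 were. In simulated CH3+5 libraries with an assumed coefficient of variation of 0.1, 389 of 15717 unchanged genes passed the rule. With a mean of at least 5 CPM over the libraries, a filter unlike the one above, 138 of 11116 passed. The real pair varied less beyond counting error, with a coefficient of variation of 5.09% in genes with at least 100 counts. The simulated numbers are therefore not the noise level of this pair.

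No cell cycle gene of either list passed in CH3+5 (medians 0.02 for G1/S and 0.02 for G2/M). Of 50 p53 targets only the oxidoreductase gene TP53I3 was higher, at 0.63 (median -0.01, percentile 18.5), and of 11 pro-apoptotic BCL2 relatives 0 passed (median -0.05). Every list median lay within the central 95% of its random lists, from -0.29 for endothelial genes to 0.20 for histones. Under alternatives, 3 medians left that range: histones at 0.16 with the deposited FPKM (percentile 99.5), and mismatch repair at -0.11 (percentile 1.75) and ribosomal protein genes at 0.03 (percentile 99.3) after removal of GC and length trends. Single members that passed were HIST1H2AG at 0.82, the interferon-stimulated IFI44 at 1.91, the proteasome genes PSMB9 at -1.28 and PSMB10 at 0.66, the immediate early EGR3 at 1.0, the hypoxia gene ANKRD37 at -0.82, the epithelial ELF3 from 16 to 37 counts and KRT20 from 1 to 8, the actin-binding TAGLN at -0.92 and the collagen gene COL6A3 from 8 to 0 counts. In 17 of the 25 lists 0 genes passed in this pair.

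Among protein-coding genes with at least 100 counts in the higher library, the largest rises in this pair included the lipid phosphatase relative PLPPR4 at 1.11, AC126755.2 at 1.04, BEND6 at 0.96, the synaptotagmin SYT3 at 0.92 and the choline transporter relative SLC44A3 at 0.89. The largest falls among such genes included the dynein gene DNAH10 at -1.18, TAGLN, the transcriptional repressor ZGPAT at -0.92, DENND6B at -0.90, FRMPD3 at -0.90 and the zinc finger gene ZNF576 at -0.89. The rule also named EIF3C at -1.76, UBE2V1 at -0.92, TBC1D3D at 1.12 and NOMO3 at 0.90, which have near-identical copies or overlap a neighbour, so the assignment of their reads is uncertain.

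Set side by side, the parental line showed the p53, cytokine and cell cycle changes at a size that the CH3+5 pair did not. The difference in the change of WRN itself was -2.26 (-2.60 to -1.96), and every other difference was measured alongside it. It was 1.70 for BBC3 (1.41 to 2.0) and 2.72 for CDKN1A (2.64 to 2.79). By the size rule on the difference, 1641 genes had a more positive change in the parental line and 2289 a more negative one. These intervals hold counting error only.

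Of the p53 targets, 33 of 50 had a more positive change in the parental line and 1 a more negative one (median difference 0.87, percentile 100). The same direction held for 15 of 19 immediate early genes (median 1.33), 10 of 14 NF-kB and cytokine genes (1.01), 12 of 22 TGF-beta targets (0.81), 9 of 19 ATF4 and unfolded protein response genes (0.49) and 4 of 8 histones (0.76). The opposite direction held for 29 of 34 G1/S genes (-1.07), 34 of 34 G2/M genes, 17 of 28 homologous recombination genes (-0.70), 9 of 20 cholesterol genes (-0.51) and 6 of 22 interferon-stimulated genes (-0.37). Against their lists went 2 TGF-beta targets, 1 ATF4 and unfolded protein response gene, 1 cholesterol gene and 1 interferon-stimulated gene. Pro-apoptotic (0.21, percentile 89.0) and Wnt target (-0.14, percentile 12.3) medians lay inside the central 95% of random lists. The interferon median lay inside the central 95% of random lists with the deposited FPKM (-0.16), with total counts and for protein-coding genes only. Among the most positive differences of single genes were CXCL8 at 5.50, EID3 at 4.31, KRTAP2-3 at 4.19, ATF3 at 3.56, the fibrillin gene FBN2 at 3.36 and GRAMD1B at 3.05. RGPD6, which has near-identical copies, was at 3.01. Among the most negative were METTL7A at -4.80, CALB1 at -3.67, AQP3 at -3.63 and PRIMA1 at -3.25, together with 4 genes near or at 0 counts in the parental siWRN library. Those were the synaptic PLPPR4 (16 to 0 counts), the matrix gene SPARC (33 to 0), the growth factor binding protein IGFBP3 (27 to 1) and PNMA2 (26 to 0).

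Genes changed in both lines were few. Higher in both siWRN comparisons were 49 genes, against 35.5 for independent sets of these sizes, and lower in both were 139, against 86.9. Opposite changes were seen in 80 genes that were higher in the parental line, against 53.3 for independent sets, and in 84 that were lower there, against 57.9. Across genes, which are not independent replicates, the log2 changes of the lines had a Pearson correlation of 0.029 and a Spearman correlation of 0.033. In the additive model 0 genes had an siWRN effect common to both lines (edgeR quasi-likelihood test, smallest adjusted p 0.962), with 313 genes at an unadjusted p under 0.05. DESeq2 gave 0 genes with 282 at that unadjusted level, and limma-voom 0 with 441. Each of these numbers is below a share of 0.05 of the 15917 genes, so none is an excess of small p-values. Without the filter on low counts edgeR gave 60 higher and 64 lower genes. WRN was at -1.35 in that model with an adjusted p of 0.962, and in the p53, G1/S and G2/M lists 0 genes passed over all genes and 0 when adjusted over the list alone. In the other lists 0 passed over all genes, and adjusted over the list alone only the endothelial PECAM1 did, on 66, 0, 4 and 0 counts. The error term of that model includes the difference between the lines, which for WRN itself was large, so 0 calls do not show that no change was shared.

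**Figure D2:**
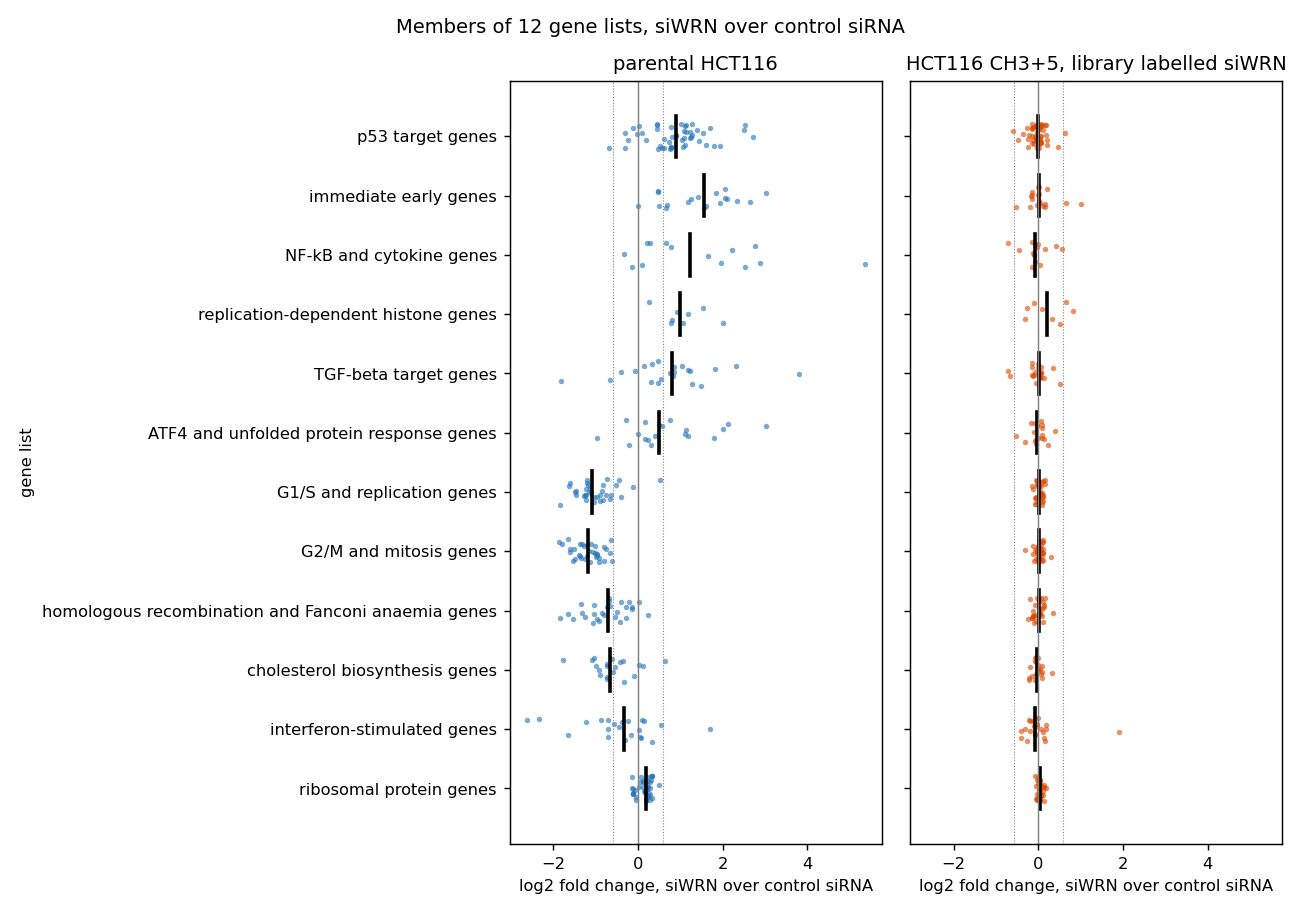
Log2 fold change (horizontal axis) of the members of 12 gene lists (points) for siWRN against control siRNA in the parental line and in CH3+5, with each list's median as a black bar and dotted lines at a fold change of 1.5 in each direction. In the parental line the median of the p53 list lay at 0.91 and that of the G2/M list at -1.18, and in CH3+5, where WRN was not depleted, they lay at -0.01 and 0.02.

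Under control siRNA the lines themselves differed in cell identity. In CH3+5 most epithelial and colon genes were lower and most TGF-beta target and Wnt target genes higher than in the parental line, with a few members of the last 2 lists lower, while mesenchymal genes were mixed, with a median that depended on the processing. Most of its cholesterol synthesis genes were lower and most of its mitosis genes higher. The median change of the genes on each transferred chromosome was above 0. In total 2687 genes were higher and 2748 lower in CH3+5.

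Of 14 epithelial and colon genes 11 were lower in CH3+5 and 0 higher (median -1.82, percentile 0). They included the cadherin gene CDH1 at -4.33, ELF3 at -6.26, and the epithelial regulator GRHL2, which fell from 414 to 3 counts. RAB25, an epithelial trafficking gene, fell from 695 to 3 counts, 215 times (73.2 to 1044), S100A14 was at -6.69 and the gastric annexin gene ANXA10 fell from 465 to 0 counts, at least 144-fold lower against the floor of 3 counts per library. The protocadherin gene PCDH7 was 458 times lower (179 to 1683), the adhesion receptor ADGRF1 435 times (149 to 2112) and the growth factor carrier FGFBP1 253 times (45.0 to 10030). DPEP1, a dipeptidase gene, was at least 59.3-fold lower. Mesenchymal genes were higher in 5 of 10 cases and lower in 2 (median 0.77, percentile 99.8), with vimentin (VIM) at 3.70, the repressor ZEB1 at 2.50 and S100A4 at -3.76. The mesenchymal median was 0.13 with the deposited FPKM and 0.34 without genes of chromosomes 3 and 5, both inside the central 95% of random lists. TGF-beta targets were higher in 13 of 22 cases and lower in 3 (median 0.89, percentile 100), with CTGF at 6.70, PMEPA1 at 5.33 and THBS1 at 4.34. The TGF-beta induced matrix gene TGFBI was 1067-fold higher on 1 count in the parental line (191 to 42190), and the matrix gene SPARC 282-fold higher (201 to 410), both lying on the transferred chromosome 5.

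Among the largest rises were TM4SF1, a tetraspanin-like membrane gene, from 0 to 3538 counts, at least 1272-fold, the growth cone gene BASP1, at least 572-fold, NNT, the mitochondrial transhydrogenase, at least 533-fold, and DOCK2, at least 264-fold. The kinase gene DCLK1 was 710-fold higher (455 to 1180) and FGD5 1002-fold on 1 count (179 to 39630). Of these, TM4SF1 and FGD5 lie on chromosome 3 and BASP1, NNT and DOCK2 on chromosome 5, which were transferred. Wnt targets were higher in 8 of 15 cases and lower in 2 (median 0.59, percentile 99.9), SP5 at 2.21 and the Wnt inhibitor DKK1 at 2.04 being higher and RNF43, which removes Wnt receptors, lower at -5.26. EGFR ligands, a group chosen after its values were seen, were lower for 4 of 6 measured genes and higher for 1, HBEGF at 1.07, the lower ones including EREG at -6.20 (17709 to 222 counts) and AREG at -5.62 (3974 to 73 counts).

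Mitosis genes were higher in 23 of 34 cases (median 0.77, percentile 100), including the securin gene PTTG1 at 1.35 and CDC25C at 1.25, and G1/S genes in 4 of 34 (median 0.22, percentile 95.5). Cholesterol synthesis genes were lower in 15 of 20 cases and higher in 1 (median -0.82, percentile 0), with SQLE at -2.16 and FDFT1 at -1.66. The p53 targets were lower in 17 of 50 cases and higher in 4 (median -0.22, percentile 0.08), and BBC3 was lower at -0.89 (-1.12 to -0.68). BIK at -1.66 and BAX at -0.70 were lower and BAK1 at 0.64 higher among the pro-apoptotic genes (median -0.42, percentile 1.60, but -0.14 and inside the random range with the deposited FPKM), and the anti-apoptotic BCL2 at 1.73, BCL2L1 at 1.02 and MCL1 at 0.63 were higher (median 0.82, percentile 99.1). Immediate early genes were higher in 8 of 19 cases and lower in 1 (median 0.41, percentile 99.1), with CYR61 at 3.40, FOSL1 at 2.35 and MYC at -2.20. That median was 0.29, inside the random range, without genes of chromosomes 3 and 5. Also higher were NF-kB and cytokine genes in 6 of 14, with 2 lower (median 0.58, percentile 99.7), including BIRC3 at 2.29. Histones were lower in 5 of 8 cases (median -1.11, percentile 0.22), and mitochondrially encoded mRNAs in 5 of 13 (median -0.51, percentile 0). Of 40 ribosomal protein genes 0 passed, but their median of -0.24 lay below all random lists (percentile 0).

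Between the lines, interferon-stimulated genes were higher in 7 cases and lower in 4 (median 0.19), with CMPK2 at 2.17 and OASL at -2.09. In antigen presentation, hypoxia, and ATF4 genes the counts were 2 higher and 2 lower, 6 and 3, and 3 and 3, with ERAP1, which trims peptides, at 1.59, the cystine transporter SLC7A11 at 1.83 and ASNS at -1.33. Homologous recombination genes were higher in 4 cases and lower in 1 (median 0.14), BARD1 at 1.14 and FANCD2 at 1.03 among the higher. In mismatch repair 3 of 8 genes were higher and 0 lower (median -0.05), and among RecQ helicases RECQL was higher at 0.97. Leukocyte genes were higher in 1 case and lower in 2, endothelial genes in 1 and 3, and the reference genes GUSB, ACTB and B2M were higher at 1.03, 0.72 and 0.71.

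Expression was also compared by chromosome. Under control siRNA the 940 measured genes of chromosome 3 had a median log2 difference of 0.58 and the 757 of chromosome 5 one of 0.40, each at percentile 100. On chromosome 3, 452 genes were higher and 63 lower, and on chromosome 5, 295 and 71. In the siWRN libraries the medians were 0.57 and 0.41. Chromosomes 16 at -0.27, 14 at -0.21, 19 at -0.15, 22 at -0.12, 17 at -0.10, 20 at -0.10 and 6 at -0.07 lay below the central 95% of their random lists, and chromosomes X at 0.13 and 2 at 0.05 above it. After removal of GC and length trends chromosomes 22 and 2 lay inside it, and chromosome 19 was at -0.07. Along chromosome 3, 18 of 19 windows had a median above 0.3 in either pair of libraries. All its windows ranged from 0.18 to 0.80 under control siRNA and from -0.14 to 0.91 in the siWRN libraries. Along chromosome 5, 12 of 18 windows were above 0.3 under control siRNA, from 0.04 to 1.16 over all windows.

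**Figure D3:**
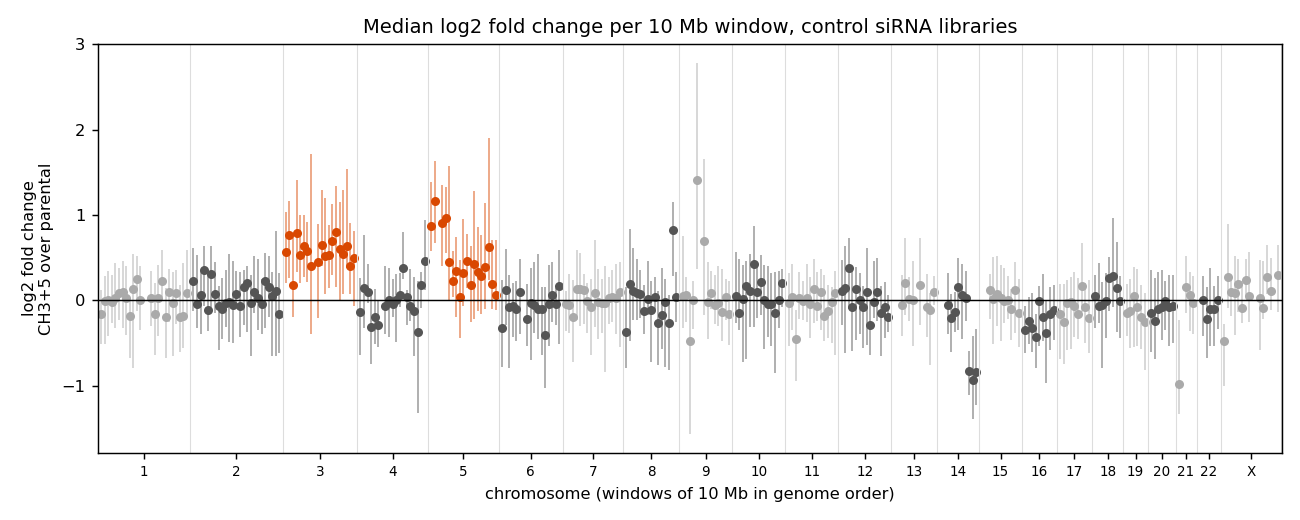
Median log2 difference between CH3+5 and the parental line under control siRNA (vertical axis) in windows of 10 Mb with at least 10 measured genes, in genome order, with lines from the lower to the upper quartile of the genes and chromosomes 3 and 5 in orange. On chromosome 3, 18 of 19 windows lay above 0.3, and on chromosome 5, 12 of 18.

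The line effect common to both siRNAs was tested with the additive model. With edgeR, 1606 genes were higher and 1179 lower in CH3+5, the smallest adjusted p being 0.000131, and both libraries of CH3+5 enter that estimate. The libraries of a line differ in siRNA and are not replicate cultures, so these p-values do not measure variation between cultures. MSH3 was at 2.0 (adjusted p 0.00350) and BBC3 at -1.76 (0.0282), while CDKN1A had an adjusted p of 0.112. The value for BBC3 includes its rise in the parental siWRN library. Among the smallest adjusted p-values were TM4SF1, the transglutaminase TGM2 at 4.58, TM4SF18 at 6.31, the protease inhibitor SERPINA1 at 5.77 and TGFBI at 8.89 in the higher direction. In the lower direction they were ADGRF1, RAB25, EREG at -6.46, the phosphodiesterase PDE4B at -5.61 and MAL2, a gene of epithelial transport, at -5.22. In the G2/M list 28 genes were higher over all genes and 33 when adjusted over the list alone, and in the epithelial list 10 and 13 were lower. The p53 list had 1 higher and 15 lower over all genes, and 1 and 19 adjusted over the list alone. These counts average both siRNAs and include the response of the parental siWRN library: the G2/M median between the lines was 0.77 under control siRNA and 1.94 in the siWRN libraries, and the p53 median -0.22 and -1.29. DESeq2 called 1439 higher and 948 lower genes and limma-voom 1706 and 1334.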

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

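Of the tests in this part, those of WRN depletion, of mismatch repair correction and of other effects of the siRNA were chosen after the results they measure were seen. In 12 reported genes, 2 of them (BTC and EGF) chosen after their values were seen, the changes passed the size rule in opposite directions in the lines, each on 1 library against 1. None of these differences was tested against variation between cultures, and WRN passed the size rule only in the parental line. Lower in parental siWRN and higher in the CH3+5 library labelled siWRN were METTL7A (difference -4.80, from -3.47 and 1.33), PLPPR4 (-4.21, from -3.10 and 1.11), KRT20 (-2.86, from -1.19 and 1.67), EGF (-2.71, from -1.77 and 0.94), ELF3 (-2.04, from -1.02 and 1.02), BTC (-1.89, from -0.83 and 1.05) and SYT3 (-1.66, from -0.75 and 0.92). The reverse held for COL6A3 (4.38, from 2.03 and -2.35), EID3 (4.31, from 2.65 and -1.66), GRAMD1B (3.05, from 0.62 and -2.43), RGPD6 (3.01, from 2.15 and -0.86) and TAGLN (2.07, from 1.15 and -0.92). Low counts lie behind several of them: COL6A3 had 4 and 20 counts in the parental line and 8 and 0 in CH3+5, KRT20 1 and 8 counts in CH3+5, EGF 9 and 1 in the parental line, BTC 12 and 29 in CH3+5, and PLPPR4 16 and 0 in the parental line. RGPD6 has near-identical copies.

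The library labelled CH3+5 siWRN differed little from its control, with p53 targets and cell cycle genes near 0. Depth argues against a loss of sensitivity, since 33 of the 35 p53 targets that were higher in the parental line had a CH3+5 interval whose upper end lay below 1.5-fold. Whether both CH3+5 libraries came from 1 RNA stays open: the variance of the log ratio was 5.40 times its Poisson value in genes with at least 1000 counts, above the bound of 1.5 written beforehand, but that bound was too low, because separately prepared libraries of 1 RNA could exceed it too. WRN at 0.83 of its control is consistent with a failed knockdown or a wrong label as the reason for the small change. Mismatch repair correction as the reason cannot be told apart from this, because the change of WRN itself differed by -2.26 between the lines. It can also not be told apart from the many other genes that differed between the lines under control siRNA.

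In the parental line, most p53 targets were higher and most cell cycle genes lower in the siWRN library. Trends with GC content or gene length are argued against, as the median of the p53 list was 0.89 after both trends were removed. Effects of the siRNA or its transfection other than loss of WRN stay open, because the lines' changes had a correlation of 0.0287 across genes but WRN did not fall in both, which makes that test void. Loss of WRN may be the reason, and differences between single cultures in growth or density were not tested.

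The genes of chromosomes 3 and 5 had medians above 0 in CH3+5 against the parental line. A trend with GC content or gene length is argued against, since the median of chromosome 3 was 0.57 after both trends were removed. A share of 0.947 of the windows of chromosome 3 lay above 0.3, which met the value written down for extra copies along all of it. The window from 20 to 30 Mb was the exception, at 0.18 under control siRNA and at -0.14 in the siWRN libraries, so a gain there was not seen. On chromosome 5 the share was 0.667, between the values written down for a whole extra chromosome and for none, so extra copies of all of it or of parts cannot be told apart.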

How the results depend on the processing

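The alternatives that removed GC and length trends or left out genes of chromosomes 3 and 5 were chosen after the data were seen. Of the recomputed values of the main comparisons, 133 kept their side of the rule, or lay within 1.5 times the reported count. Another 7 became stronger and 24 weaker. Among these, a change of direction could be recorded only for medians of lists and chromosomes outside their random range, and none was seen. For single genes, other lists and chromosomes the numbers kept, stronger and weaker were 680, 7 and 19. In parental siWRN the counts (higher and lower) were 953 and 1547 at 5 CPM, 663 and 1332 at 2-fold, and 889 and 1201 with FPKM. In CH3+5 they were 767 and 979 without a filter, 96 and 118 at 5 CPM, 191 and 301 at 2-fold, 204 and 278 for protein-coding genes, and 110 and 155 with FPKM. The difference between lines gave 803 and 1297 at 2-fold, and 1089 and 1372 with FPKM. CH3+5 over parental gave 1792 lower at 5 CPM, 1365 and 1568 at 2-fold, and 1504 lower with FPKM. The stricter rule accounts for the counts at 2-fold. The 5 CPM filter keeps 11957 of 15917 genes, a smaller cut than that in the CH3+5 counts. The protein-coding counts equal the 204 higher and 278 lower protein-coding genes among the main CH3+5 calls, so leaving out other genes accounts for them. The FPKM counts also used no counting interval. For the filters and FPKM the cause was not tested. The G1/S median between the lines was 0.25 after GC and length trends were removed, at percentile 98.1 against 95.5, and the cause was not tested. In the additive model without a filter, 60 higher and 64 lower genes had an siWRN effect, all 124 of them past the usual filter, and 2463 and 1780 a line effect, for which the cause was not tested. FPKM with limma gave 926 and 659 for the line effect, also of untested cause. The additive model already compares the siRNAs within each line. No further pairing or block could be added, because each group holds 1 library. For the same reason no library could be left out and no labels permuted within groups. Leaving out the library labelled CH3+5 siWRN would leave the additive model no residual degree of freedom. Depth limits low genes: 1 CPM is 18.6 to 21.3 counts.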

Other observations

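The counts by chromosome part, the groups of oxidative stress genes and EGFR ligands, and the test on silent genes were chosen after the values were seen. Genes with at most 3 counts in both parental libraries and at least 5 CPM in both CH3+5 libraries numbered 33, of which 8 lie on chromosome 3 and 19 on chromosome 5. That is 81.8% (exact 95% interval 64.5 to 93.0), against 10.7% of all measured genes, 1697 of 15917. Genes silent in the parental line may therefore be expressed from the transferred copies, as a hypothesis found and tested on the same libraries. In the reverse direction 10 genes were silent in CH3+5, with 0 on those chromosomes, and the exact interval of that share, 0 to 30.9%, includes the share of all measured genes.

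On chromosome 5 the 135 measured genes from 0 to 50 Mb had a median of 0.91 between the lines under control siRNA, and the 622 from 50 to 190 Mb one of 0.31. In the siWRN libraries the values were 1.04 and 0.32. On chromosome 14 the 141 genes from 80 to 110 Mb had a median of -0.87 (-0.70 in the siWRN libraries), while the 364 others had one of -0.03.

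Of 7 oxidative stress genes, 6 were higher in the parental siWRN library (median 1.02), HMOX1 at 2.77, the thioredoxin reductase TXNRD1 at 1.27, SRXN1 at 1.21, GCLC at 1.02, SLC7A11 at 0.76 and GCLM at 0.74, and NQO1 was at 0.49. In CH3+5 0 of them passed the size rule (median 0.01). Among 6 EGFR ligands, AREG at 1.33 and HBEGF at 1.85 were higher and BTC at -0.83 and EGF at -1.77 (9 to 1 counts) lower in the parental siWRN library. In the CH3+5 library labelled siWRN, BTC at 1.05 and EGF at 0.94 were higher and 0 were lower.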
